A study of Mus musculus with 16 samples.

How the data were processed

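Hearts of 10-week-old male C57BL/6 mice were compared after sham surgery and after the left anterior descending coronary artery had been tied for 30 min and released for 6, 24 or 72 h, per the labels, with 4 hearts in each of 4 groups and 1 array per heart. The deposited table holds 1 log2 expression value for each of 28846 probe sets on each of 16 arrays. Per the submitters' processing notes, the authors used Affymetrix Expression Console to make these values; its version, the summarization method and any filter are not given in the sources used here. The log base is not stated and was taken as 2, the base that this software writes. The deposited log2 values ran from 1.83 to 19.82, none was below 0, and the array medians lay between 5.84 and 5.95, so the arrays had been brought to a common scale before deposit and were used as deposited. A maximum of 19.82 is above the log2 range of scanner intensities, and folds are therefore reported on the authors' scale, which may be stretched. The design text names another Affymetrix mouse array than the one whose transcript cluster identifiers the table carries, and the identifiers were followed. The series title lists hours that differ from the sample labels, and the labels were followed. Replicates carry numbers that no 2 groups share, so no pairing was used. The highest correlation between 2 arrays was 0.994, and 0 pairs of arrays were identical.

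Probe sets were named from the platform annotation, with symbols updated through the reference gene table. Of 28846 probe sets, 19572 had 1 gene symbol, 0 had several and 9274 had none here, the last made up of 5222 negative controls, 1324 positive controls, 31 other Affymetrix controls and 2697 further transcript clusters, which stayed out of the tests. Where a gene had more than 1 probe set (55 genes), the probe set with the highest mean over all arrays was kept, which left 19505 genes. No filter on dim genes was applied. The table has no detection calls, and the 75th percentile of the negative controls, a signal of 6.76, was used to name levels near background. No genome build is given in the sources used here, so no coordinates are printed.

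Group means were fitted over all 16 arrays with lmFit and moderated with eBayes in limma 3.58.1 under R 4.3.3, with 12 residual and 6.943 prior degrees of freedom, for 6 comparisons: each time with sham, and each pair of times. P-values were adjusted by the Benjamini-Hochberg method over 19505 genes with a threshold of 0.05, and an F test over the 4 groups was adjusted likewise. The number of arrays limits the precision: the median SE of a log2 change was 0.183, with 5th and 95th percentiles of 0.135 and 0.279. Of 50 gene lists fixed by name, 756 of 814 genes were matched, 5 of them through an older symbol, and 49 lists had at least 5 measured members and were tested with camera at a preset correlation of 0.01 between genes, with an estimated correlation as the alternative. Counts of members were also adjusted over the list alone. Array measures and control probe sets were compared by two-sided exact permutation tests. Time classes used the tests between times. Overlaps of calls were set beside 50 simulations in which all 16 arrays, sham included, were drawn around the sham means without any change. They were also set beside splits of the sham arrays. Figures were drawn with matplotlib 3.10.9.

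The design, the gene lists, the rule for naming genes and the first set of alternative settings were fixed before the data were examined. The rule names, in each comparison with sham, the 10 largest rises and the 10 largest falls among genes past the threshold whose 4 and 4 arrays did not overlap and whose higher group mean reached the median of all probe sets, and 5 each way between times. It also names 14 genes fixed by name, of which 13 were measured, and up to 4 members of each list described with the largest change past the threshold. Predicted genes without a proper symbol were passed over. That set held quantile normalization, median centring of arrays, the mean of a gene's probe sets, filters at the 25th percentile and at the median of each array, trend and robust settings of eBayes, array weights, fits of only the 2 groups compared, the estimated correlation, a minimum of 2-fold for classes, and leaving out each of the 16 arrays in turn. Centring on the 4 hybridization spike-ins, centring on the 4 probe sets of the poly-A spike-ins and a filter at the 75th percentile of the negative controls were added after the data were seen.

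The fit and the list test were tested on simulated data for the comparison of 24 h with sham, with 200 of 19505 genes changed. Of 50 genes per size, 14% were recovered at a log2 change of 0.5, 88% at 1, 100% at 2 and 100% at 3, with 12 false calls among 163, and a changed list of 20 genes was found while 0 of 200 unchanged lists passed. Genes were simulated without correlation, so the list result does not cover lists whose genes move together. In the data the estimated correlation ended 134 of 153 list calls.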

Results

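Gene expression was measured in hearts of 10-week-old male C57BL/6 mice after ischemia and reperfusion. The left anterior descending coronary artery, which supplies the anterior wall of the left ventricle, was tied for 30 min and reopened for 6, 24 or 72 h, and sham-operated mice served as controls. RNA from 4 hearts per group was hybridised to 16 Affymetrix arrays, and 19505 genes were tested. The comparisons ask which transcripts differ from sham at each time of reperfusion, and which differ between the times. The treatment labels of the sham arrays give no hours, and the same sham arrays serve every time. A change with time after surgery itself therefore cannot be told from one with reperfusion. The series title names another set of hours than the sample labels and the study's own design text, whose 6, 24 and 72 h are used here. With 4 arrays per group, the number of arrays sets the precision: the median SE of a log2 change was 0.183. Below, each change is a difference of mean log2 signal ± SE between 4 and 4 arrays, and "rose" and "fell" are used where the adjusted p of limma's moderated test lay below 0.05. The values reach 19.82, above what a scanner's plain log2 intensity allows, so folds hold on the deposited scale, which may stretch them. Means below 6.76, the 75th percentile of the negative control probe sets, are named as below background, and the size of a change to or from such a mean depends on the background. The label names dim levels and does not say that a transcript was absent. Other controls lay lower: the median of the negative controls was 5.37, and 23 GC background probe sets had array means of 4.35 to 4.45. The median of genes on each array lay there too, at 5.87 to 6.07.

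The 4 groups lay apart on the first 2 principal components, which held 37.2% and 25.4% of the variance between arrays. Replicate 17 of the 24 h group had a score of 10.8 on the first component, against 35.1 to 40.7 for the other 24 h arrays. Replicate 16 of that group had a mean of 2.00 for 10 atrial markers relative to sham, against -0.43 to 0.04 on the other 24 h arrays, with the atrial myosin light chain Myl4 at 15.22 against 7.34 to 7.93. At 72 h Myl4 was at 9.76 and 9.44 on replicates 21 and 23, against 7.69 and 7.75 on the other 2. Of all genes, 8677 (44.5%) differed among the 4 groups. The hybridization spike-ins, control transcripts added to every array, had a mean log2 signal of 10.54 ± 0.06 (SD, n = 4) in sham and were 0.22 higher at 6 h (two-sided exact permutation p = 0.0286, the smallest p that 4 against 4 arrays allow), -0.31 at 24 h relative to sham (exact p = 0.0571) and -0.50 at 72 h relative to sham (exact p = 0.0286). After Benjamini-Hochberg adjustment over 42 tests of array measures, these p-values were 0.0667, 0.114 and 0.0667. The poly-A spike-ins, which are added to the RNA before labelling, moved in part otherwise: they were 0.34 higher at 6 h (exact p = 0.0286, adjusted 0.0667), 0.10 higher at 24 h (exact p = 0.314) and -0.19 at 72 h relative to sham (exact p = 0.143). The median of the positive control probe sets was -0.23 at 6 h and 0.21 at 24 h relative to sham (each exact p = 0.0286, adjusted 0.0667) and 0.03 at 72 h (exact p = 0.143). Centring each array on the hybridization spike-ins (below, spike-in centring) moved the median change of all genes against sham from -0.04 to -0.26 at 6 h, from -0.07 to 0.24 at 24 h and from -0.09 to 0.40 at 72 h. Centring on the poly-A spike-ins moved it to -0.37, -0.16 and 0.09. Both alternatives were added after the data were seen. The changes below are on the deposited scale. Medians of the lists described against sham that turned their sign under either centring are given beside the lists.

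**Figure D1:**
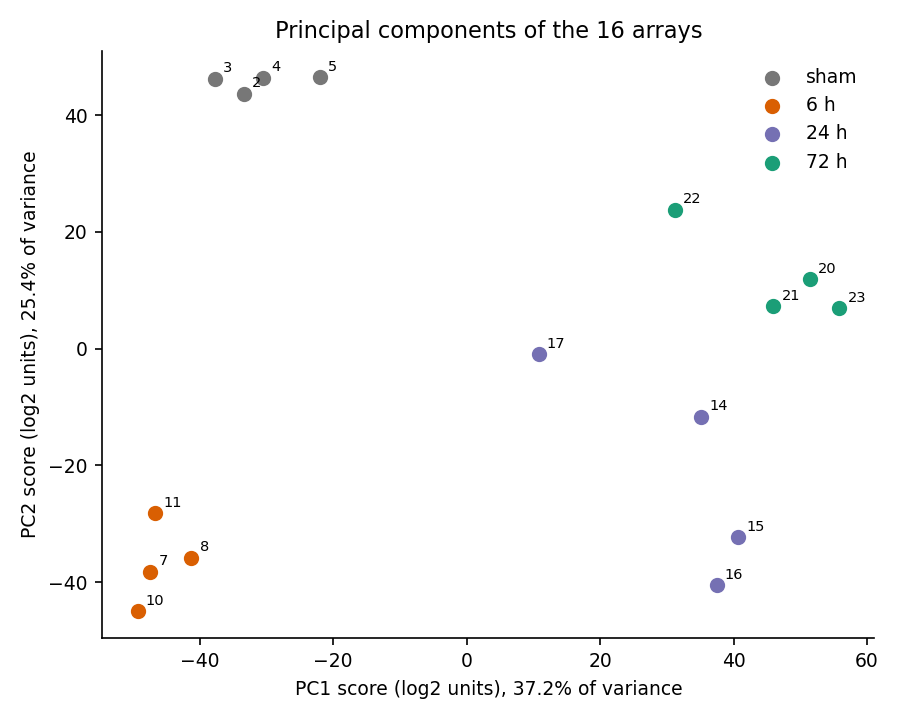
Scores of the 16 arrays on the first (37.2% of variance) and second (25.4%) principal components of log2 signal over all genes, coloured by group and numbered by replicate. The 4 groups occupy separate areas, and replicate 17 of the 24 h group lies at 10.8 on the first component, away from the other 24 h arrays at 35.1 to 40.7.

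At 6 h of reperfusion, immediate early, cytokine, chemokine and matrix protease genes were far above sham. Thbs1, which encodes the matricellular protein thrombospondin 1, rose by 8.92 ± 0.43. Hbegf, a ligand of the EGF receptor, rose by 7.25 ± 0.43, and Ccn2, the connective tissue growth factor gene, by 7.16 ± 0.50. The cytokine Il6 rose by 6.98 ± 0.47 and the neutrophil-attracting chemokine Cxcl5 by 6.46 ± 0.45. Among falls, Pirt, a regulator of the TRPV1 channel in sensory neurons, changed by -3.49 ± 0.30, the apelin receptor Aplnr by -3.47 ± 0.30, the clock gene Per3 by -3.25 ± 0.27 and Ppp1r3b, a subunit that directs protein phosphatase 1 to glycogen, by -2.97 ± 0.31. In sham, Thbs1, Hbegf, Il6 and Cxcl5 were below background, as were Pirt and Ppp1r3b at 6 h and Cdk1 and Psmb8 in both groups. Nppb, the gene of B-type natriuretic peptide, rose by 3.56 ± 0.37, while Nppa had a change of 0.01 ± 0.28 (limma adjusted p = 0.988), Col1a1 one of -0.37 ± 0.22 (0.301), Myh7, the fetal myosin heavy chain gene, one of -0.27 ± 0.24 (0.515), Cdk1 one of 0.12 ± 0.30 (0.859) and Psmb8 one of 0.01 ± 0.20 (0.981), and Myh6, the adult heavy chain gene, had a mean of 17.86 in both groups. Under poly-A centring Col1a1 (-0.71, limma adjusted p = 0.0240) and Myh7 (-0.61, limma adjusted p = 0.0442) passed as lower.

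Several lists of functionally related genes moved together at 6 h. Of 15 immediate early genes, 14 rose (14 adjusted over the list alone; camera adjusted p = 2.32e-19). Myc rose by 6.50 ± 0.43, Atf3 by 6.07 ± 0.39 and Egr1 by 3.67 ± 0.51, all transcription factors. Of 19 genes of inflammatory cytokines and gp130 signalling, 15 rose (15 adjusted over the list alone; camera adjusted p = 4.26e-19). Besides Il6, the cytokine receptor gene Il4ra rose by 4.44 ± 0.35 and the alarmin Il33 by 4.19 ± 0.33. Of 20 chemokines, 14 rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 2.78e-12). Besides Cxcl5, the monocyte attractant Ccl2 rose by 6.04 ± 0.41. Matrix proteases and their inhibitors rose in 13 of 17 cases (13 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.09e-12). Timp1 rose by 6.04 ± 0.50, Adamts1 by 5.31 ± 0.31 and Plaur, the urokinase receptor gene, by 5.23 ± 0.49. Of 19 genes of the fetal and mechanical stress list, 14 rose (14 adjusted over the list alone; camera adjusted p = 3.60e-16). Besides Ccn2, Ccn1 rose by 5.24 ± 0.40 and the intercalated disc gene Xirp1 by 4.56 ± 0.16. In sham, Myc, Il33, Ccl2, Timp1 and Plaur were below background.

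Of 12 genes known to respond to glucocorticoids, 10 rose at 6 h (10 adjusted over the list alone; camera adjusted p = 6.52e-14). Lcn2 rose by 6.51 ± 0.55, Fkbp5, a chaperone of the glucocorticoid receptor, by 4.36 ± 0.42 and Pdk4, an inhibitor of pyruvate oxidation, by 4.01 ± 0.28. Of 11 endothelial activation genes, 9 rose (9 adjusted over the list alone; camera adjusted p = 1.54e-08), led by the adhesion receptors P-selectin (Selp, 6.21 ± 0.47) and E-selectin (Sele, 2.75 ± 0.31). These 7 list calls held with an estimated correlation between genes, with adjusted p-values from 0.00409 for the glucocorticoid list to 0.0374 for endothelial activation. Neutrophil markers rose in 12 of 13 cases (12 adjusted over the list alone; camera adjusted p = 1.47e-13, and adjusted p = 0.107 with an estimated correlation). Retnlg rose by 6.48 ± 0.62, S100a8 by 5.03 ± 0.78 and the neutrophil collagenase Mmp8 by 4.26 ± 0.48. Of 18 monocyte and macrophage markers, 9 rose (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.14e-05, and adjusted p = 0.534 with an estimated correlation). The integrin Itgam rose by 3.29 ± 0.39 and the scavenger receptor Msr1 by 2.72 ± 0.38. Ribosome biogenesis genes rose in 15 of 19 cases (15 adjusted over the list alone; camera adjusted p = 4.42e-12, and adjusted p = 0.1004 with an estimated correlation). Rrp12 rose by 2.65 ± 0.22 and Nop58 by 2.34 ± 0.26. Under spike-in and poly-A centring 10 and 9 ribosome biogenesis genes and 7 and 6 endothelial activation genes were higher, with 1 of the latter lower in each. In sham, Selp, Sele, Retnlg, S100a8, Mmp8, Itgam and Msr1 were below background.

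Antioxidant, heat shock and apoptosis genes were higher at 6 h in part. Of 19 NRF2 and antioxidant genes, 9 rose and 1 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.000783, and adjusted p = 0.0943 with an estimated correlation). Heme oxygenase Hmox1 rose by 6.20 ± 0.63 and the metallothionein Mt2 by 3.92 ± 0.43, while the list median of 0.32 became -0.02 under poly-A centring, with 6 higher and 3 lower. Of 13 heat shock and chaperone genes, 6 rose and 1 fell (6 and 2 adjusted over the list alone), with Hspa1a at 4.90 ± 0.72 and Hspb1 at 3.56 ± 0.39. The camera adjusted p of this list was 0.0284 (adjusted p = 0.442 with an estimated correlation), and it was 0.0517 over genes brighter than the array median and 0.0525 without replicate 8 of the 6 h group, where the list median went from 0.24 to 0.13; under poly-A centring this median was -0.10, with 5 higher and 4 lower. Among 17 apoptosis and p53 genes 6 rose (8 adjusted over the list alone; camera adjusted p = 2.53e-06, and adjusted p = 0.0838 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose by 4.99 ± 0.44 and the anti-apoptotic Bcl2l1 by 3.80 ± 0.25. Of 17 cardiac ion channels and transporters, 5 fell and 1 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.00435, and adjusted p = 0.533 with an estimated correlation), with 9 lower under spike-in and 11 under poly-A centring. The inward rectifier Kcnj2 changed by -2.43 ± 0.32 and the delayed rectifier Kcnq1 by -1.62 ± 0.21, whereas Kcna5 rose by 2.00 ± 0.16. Background was above the sham mean of Hspa1a and the 6 h mean of Kcnj2. None of the 24 genes of fatty acid oxidation, the 19 of the TCA cycle or the 35 of oxidative phosphorylation passed the limma test at 6 h, over all genes or adjusted over the list alone, and their median changes were -0.13, -0.11 and -0.05. Under spike-in centring 4, 1 and 1 of them were lower, and under poly-A centring 8, 4 and 4. Of 22 fibrillar matrix genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone), with a median of -0.12, a mean of 0.54 and a camera adjusted p of 0.410 for a shift upward, but 3 were higher and 5 lower under spike-in centring and 3 and 8 under poly-A centring. Postn, the periostin gene, rose by 1.02 ± 0.31 (limma adjusted p = 0.0245), a call that ended without replicate 2 of sham (limma adjusted p = 0.0535), replicate 3 of sham (0.0743) or replicate 10 of the 6 h group (0.0836), with spike-in centring (0.0605) and with poly-A centring (0.119).

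In total, 1545 genes rose and 2395 fell at 6 h, 755 and 609 of them by at least 2-fold. The 4 arrays at 6 h did not overlap the 4 sham arrays for 22.8% of genes, where chance gives 2.86%. Under spike-in centring 975 genes were higher and 3993 lower, so that 19.63% of calls were rises, against 39.2% on the deposited scale, and under poly-A centring 864 were higher and 6087 lower (12.4% rises).

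At 24 h of reperfusion, macrophage and neutrophil markers, fetal and mechanical stress genes and matrix genes were raised, and genes of oxidative metabolism were lower. Timp1, an inhibitor of matrix metalloproteinases, rose by 8.95 ± 0.50. The stretch-responsive muscle gene Ankrd2 rose by 8.21 ± 0.55 and Nmrk2, a nicotinamide riboside kinase gene, by 6.53 ± 0.48. Ccl2 rose by 6.79 ± 0.41 and Arg1, the arginase of alternatively activated macrophages, by 5.22 ± 0.53. The falls were led by the circadian repressor Ciart at -4.61 ± 0.35, the polycystin family member Pkd2l2 at -3.47 ± 0.25, the phosphatase Dusp18 at -3.29 ± 0.24, and Kcnip2, a subunit of the transient outward potassium channel, at -3.27 ± 0.27. The natriuretic peptide genes Nppb and Nppa rose by 3.58 ± 0.37 and 2.26 ± 0.28, Cxcl5 by 4.62 ± 0.45, Il6 by 3.08 ± 0.47, Cdk1 by 1.37 ± 0.30 and Psmb8 by 1.01 ± 0.20. In sham, Timp1, Ankrd2, Nmrk2, Ccl2, Arg1, Cxcl5 and Psmb8 were below background, as were Ciart at 24 h and Il6 and Cdk1 in both groups.

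Markers of macrophages and neutrophils rose at 24 h, as did matrix genes. Of 18 monocyte and macrophage markers, 17 rose (18 adjusted over the list alone; camera adjusted p = 8.89e-19, and adjusted p = 0.104 with an estimated correlation). Itgam rose by 5.29 ± 0.39, the chemokine receptor Ccr2 by 5.11 ± 0.46 and the lectin Chil3 by 4.83 ± 0.65. All 13 neutrophil markers rose (13 adjusted over the list alone; camera adjusted p = 2.52e-10, and adjusted p = 0.179 with an estimated correlation). The G-CSF receptor gene Csf3r rose by 5.28 ± 0.62 and S100a8 by 5.11 ± 0.78. Resident cardiac macrophage markers went both ways, with 3 of 12 higher and 1 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.524). Under poly-A centring 2 were higher and 2 lower. The mannose receptor Mrc1 rose by 1.39 ± 0.15 and Cd163 fell by 1.14 ± 0.23. Of 22 fibrillar matrix genes, 17 rose (18 adjusted over the list alone; camera adjusted p = 4.62e-13, and adjusted p = 0.104 with an estimated correlation). Fibronectin (Fn1) rose by 4.72 ± 0.39, Postn by 3.10 ± 0.31 and Col1a1 by 1.49 ± 0.22. Of 11 fibroblast markers, 3 rose and 3 fell (3 and 6 adjusted over the list alone; camera adjusted p = 0.323), 2 and 3 under poly-A centring, the falls including Dpep1 at -1.81 ± 0.22 and Gsn at -1.33 ± 0.23. In sham, Itgam, Chil3, Csf3r and S100a8 were below background, as was Cd163 at 24 h.

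Genes of DNA replication, mitosis, ribosome biogenesis and the proteasome rose at 24 h. Of 19 DNA replication genes, 18 rose (19 adjusted over the list alone; camera adjusted p = 1.84e-15, and adjusted p = 0.104 with an estimated correlation). The helicase subunit Mcm3 rose by 2.80 ± 0.25 and Mcm5 by 2.52 ± 0.35. Of 24 mitosis genes, 14 rose (15 adjusted over the list alone; camera adjusted p = 6.63e-07, and adjusted p = 0.251 with an estimated correlation). The proliferation marker Mki67 rose by 2.24 ± 0.57. Ribosome biogenesis genes rose in 17 of 19 cases (17 adjusted over the list alone; camera adjusted p = 3.17e-11, and adjusted p = 0.146 with an estimated correlation), and 17 of 30 subunits of the constitutive proteasome rose (24 adjusted over the list alone; camera adjusted p = 1.62e-09, and adjusted p = 0.179 with an estimated correlation). Psma5 rose by 1.34 ± 0.16, and all 30 subunits were higher under spike-in centring but 8 under poly-A centring. Of 19 genes of the ER stress and integrated stress response, 11 rose and 2 fell (14 and 2 adjusted over the list alone; camera adjusted p = 5.08e-06, and adjusted p = 0.179 with an estimated correlation). The serine synthesis enzyme Psat1 rose by 3.58 ± 0.36 and the ER protein Creld2 by 2.52 ± 0.33. The fetal and mechanical stress list had 18 of 19 genes higher and 1 lower (18 and 1 adjusted over the list alone; camera adjusted p = 1.51e-17, and adjusted p = 0.0753 with an estimated correlation), with the LIM protein gene Fhl1 at 4.40 ± 0.29 beside Ankrd2 and Nmrk2. In sham, Mcm3, Mcm5 and Psat1 were below background.

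Transcripts of mitochondrial fuel use fell at 24 h. Of 24 fatty acid oxidation genes, 23 fell (23 adjusted over the list alone; camera adjusted p = 1.22e-12, and adjusted p = 0.179 with an estimated correlation), with a median of -0.89 (-0.58 under spike-in centring). The nuclear receptor Ppara changed by -2.39 ± 0.27, the uncoupling protein Ucp3 by -2.29 ± 0.36 and the thioesterase Acot2 by -1.82 ± 0.15. Breakdown of branched chain amino acids had 16 of 17 genes lower (16 adjusted over the list alone; camera adjusted p = 3.17e-11, and adjusted p = 0.161 with an estimated correlation), with a median of -1.11 (-0.80 under spike-in centring), including Ppm1k, the phosphatase of the branched chain dehydrogenase, at -1.88 ± 0.21. Of 19 TCA cycle genes, 16 fell (18 adjusted over the list alone; camera adjusted p = 1.50e-08, and adjusted p = 0.179 with an estimated correlation), with a median of -0.68 (-0.37 under spike-in centring) and Ogdh at -1.20 ± 0.14. Of 35 oxidative phosphorylation genes, 24 fell (30 adjusted over the list alone; camera adjusted p = 4.43e-10, and adjusted p = 0.242 with an estimated correlation), with a median of -0.50 (-0.19 under spike-in centring) and Cyc1, the cytochrome c1 gene, at -0.99 ± 0.19. Glycolysis genes went both ways, with 7 of 19 higher and 4 lower (7 and 4 adjusted over the list alone; camera adjusted p = 0.323). The lactate transporter Slc16a3 rose by 2.81 ± 0.36 and the muscle phosphoglycerate mutase Pgam2 fell by 1.46 ± 0.19, and the list median of 0.09 became -0.0017 under poly-A centring, with 5 higher and 4 lower, against 8 and 2 under spike-in centring. In sham, Slc16a3 was below background. Under spike-in centring the lower genes numbered 13 for fatty acid oxidation, 12 for branched chain amino acids, 5 for the TCA cycle and 6 for oxidative phosphorylation, and under poly-A centring 22, 16, 15 and 21. On the same arrays the monocyte and macrophage markers had a median change of 3.01.

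Muscle structure, channel and clock genes were lower at 24 h as well. Of 20 contractile genes, 11 fell (14 lower and 1 higher adjusted over the list alone; camera adjusted p = 3.09e-05, and adjusted p = 0.179 with an estimated correlation), with a median of -0.40 (-0.09 under spike-in centring, where 4 were lower and 1 higher; 9 were lower under poly-A centring), Tcap (telethonin) at -2.70 ± 0.24, the ryanodine receptor Ryr2 at -0.93 ± 0.15 and Mybpc3 at -1.03 ± 0.20. Myh6 fell by 0.58 ± 0.13 and Myh7 rose by 0.81 ± 0.24. The Myh6 call ended with spike-in centring (limma adjusted p = 0.268), and the Myh7 call without replicate 5 of sham (limma adjusted p = 0.0643). Of 17 ion channels and transporters, 11 fell and 1 rose (11 and 2 adjusted over the list alone; camera adjusted p = 3.71e-05, and adjusted p = 0.179 with an estimated correlation). The potassium channel Kcnd2 changed by -2.39 ± 0.21 and Kcnj3 by -1.91 ± 0.19. Of 14 endothelial markers, 6 fell (6 adjusted over the list alone), with the lipoprotein lipase anchor Gpihbp1 at -1.26 ± 0.19 and the VEGF receptor Kdr at -0.88 ± 0.15; the list median of -0.29 became 0.02 under spike-in centring, where 3 were lower and 3 higher. The camera adjusted p of the endothelial list was 0.0294, with 0.0532 without replicate 4 of sham and 0.0667 without replicate 15 of the 24 h group, and adjusted p = 0.251 with an estimated correlation. Of 15 circadian clock genes, 11 fell and 3 rose (11 and 3 adjusted over the list alone; camera adjusted p = 4.32e-06, and adjusted p = 0.104 with an estimated correlation). Under poly-A centring 1 was higher and 11 lower. Per3 changed by -2.44 ± 0.27 and Hlf by -2.13 ± 0.25, and Arntl, which encodes the activator BMAL1, rose by 2.17 ± 0.28. Means below background were those of Arntl in sham and of Hlf in both groups.

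Altogether 2701 genes rose and 2392 fell at 24 h, 1187 and 606 of them by at least 2-fold, and the arrays of both groups did not overlap for 25.9% of genes. Under spike-in centring 4546 genes were higher and 841 lower, 84.4% of calls being rises against 53.03% on the deposited scale, whereas under poly-A centring falls were the more numerous, with 2033 higher and 2479 lower (45.1% rises). No list call at 24 h held with an estimated correlation, the smallest adjusted p being 0.0753.

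At 72 h of reperfusion, genes of collagenous matrix, macrophages, lysosomes and cell division were raised. Col1a1, a chain of type I collagen, rose by 5.78 ± 0.22, Postn by 5.73 ± 0.31, Lox, the enzyme that cross-links collagen, by 6.07 ± 0.24, and Tnc by 7.86 ± 0.36. Timp1 rose by 8.18 ± 0.50, Gpnmb, a glycoprotein of lipid-handling macrophages, by 7.53 ± 0.38, and Mpeg1, the macrophage pore-forming protein perforin-2, by 6.39 ± 0.41. The largest falls were smaller: the desaturase Scd4 changed by -2.88 ± 0.47, Ciart by -2.44 ± 0.35, the Z-disc gene Myot by -2.38 ± 0.31, the tubulin Tuba4a by -2.29 ± 0.21 and Timp4 by -2.25 ± 0.39. In sham, Tnc, Lox, Timp1, Gpnmb, Mpeg1, Ccl2 and Cxcl5 were below background, as were Scd4 at 72 h and Il6 and S100a8 in both groups. Nppa rose by 1.70 ± 0.28, and Nppb had a change of 0.38 ± 0.37 (limma adjusted p = 0.511). Cxcl5 rose by 3.58 ± 0.45, Ccl2 by 2.81 ± 0.41 and Il6 by 2.40 ± 0.47, and Myh7 had a change of -0.43 ± 0.24 (limma adjusted p = 0.217), which became 0.06 under spike-in centring. S100a8 had a change of 1.39 ± 0.78 (limma adjusted p = 0.231), which passed under spike-in centring (1.88, limma adjusted p = 0.0440), and Myh6 had one of 0.15 (limma adjusted p = 0.451), which also passed there (0.65, limma adjusted p = 0.00623).

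Of 22 fibrillar matrix genes, 21 rose at 72 h (21 adjusted over the list alone; camera adjusted p = 1.02e-31), with a median of 3.19. Monocyte and macrophage markers rose in 17 of 18 cases (17 adjusted over the list alone; camera adjusted p = 2.77e-26), with a median of 3.86, the galectin Lgals3 at 5.63 ± 0.42 and the lipid receptor Trem2 at 5.36 ± 0.37. Of 24 mitosis genes, 23 rose (24 adjusted over the list alone; camera adjusted p = 2.77e-26), with Mki67 at 4.66 ± 0.57 and the mitotic kinase Plk1 at 4.12 ± 0.41; Cdk1, the kinase that drives entry into mitosis, rose by 2.76 ± 0.30. All 14 lysosome genes rose (14 adjusted over the list alone; camera adjusted p = 6.85e-21). The cathepsin Ctss rose by 5.37 ± 0.28 and Ctsz by 3.62 ± 0.29. Complement genes rose in 11 of 13 cases (11 adjusted over the list alone; camera adjusted p = 5.07e-15). The C1q chain C1qa rose by 3.34 ± 0.20, C1qb by 3.44 ± 0.22 and the C3a receptor C3ar1 by 4.87 ± 0.32. Of 13 pyroptosis and necroptosis genes, 11 rose (13 adjusted over the list alone; camera adjusted p = 1.86e-11). The ATP-gated channel P2rx7 rose by 2.43 ± 0.23 and Casp1 by 1.73 ± 0.22. Macrophage markers rose on the same arrays, and which cells the transcripts of this list came from was not tested. These 6 calls held with an estimated correlation, with adjusted p-values from 0.00799 for matrix to 0.0497 for mitosis. In sham, Lgals3, Trem2, Plk1, Ctsz and P2rx7 were below background, and Cdk1 was so in both groups.

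Antigen presentation and interferon-responsive genes were also higher at 72 h. Of 20 interferon response genes, 15 rose (17 adjusted over the list alone; camera adjusted p = 9.31e-11, and adjusted p = 0.133 with an estimated correlation). Oasl2 rose by 2.49 ± 0.29, Bst2 (tetherin) by 2.42 ± 0.32 and the transcription factor Irf7 by 2.30 ± 0.26. All 6 MHC class II genes rose (6 adjusted over the list alone; camera adjusted p = 5.19e-06, and adjusted p = 0.119 with an estimated correlation). H2-Aa rose by 1.78 ± 0.31. Immunoproteasome and antigen processing genes rose in 8 of 11 cases (9 adjusted over the list alone; camera adjusted p = 6.71e-06, and adjusted p = 0.0948 with an estimated correlation). The catalytic subunit Psmb8 rose by 1.44 ± 0.20 and the peptide transporter Tap1 by 1.29 ± 0.26. Of 11 fibroblast markers, 8 rose (8 adjusted over the list alone; camera adjusted p = 2.56e-06, and adjusted p = 0.133 with an estimated correlation). Mfap4 rose by 4.09 ± 0.42 and lumican (Lum) by 2.25 ± 0.26. Of 12 resident cardiac macrophage markers, 6 rose and 1 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.00307, 0.0632 over genes brighter than the array median, and adjusted p = 0.136 with an estimated correlation). Mrc1 rose by 2.30 ± 0.15 and the hyaluronan receptor Lyve1 fell by 1.56 ± 0.27. Neutrophil markers were higher in 5 of 13 cases (5 adjusted over the list alone; camera adjusted p = 0.000156, and adjusted p = 0.313 with an estimated correlation), and in 9 under spike-in centring. Means below background were those of Psmb8 in sham and of Irf7 in both groups.

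Metabolic and muscle transcripts were still below sham at 72 h on the deposited scale. Of 24 fatty acid oxidation genes, 17 fell (22 adjusted over the list alone; camera adjusted p = 4.11e-08, and adjusted p = 0.232 with an estimated correlation), with a median of -0.55 (-0.06 under spike-in centring), Ppara at -1.77 ± 0.27 and Acot2 at -1.50 ± 0.15. Of 17 branched chain amino acid genes, 12 fell (15 adjusted over the list alone; camera adjusted p = 2.56e-06, and adjusted p = 0.232 with an estimated correlation), with a median of -0.60 (-0.11 under spike-in centring). Oxidative phosphorylation had 21 of 35 genes lower (26 adjusted over the list alone; camera adjusted p = 4.11e-08, and adjusted p = 0.293 with an estimated correlation), and its median of -0.44 became 0.05 under spike-in centring. The TCA cycle had 9 of 19 genes lower (13 adjusted over the list alone; camera adjusted p = 1.60e-05, and adjusted p = 0.286 with an estimated correlation), with a median of -0.42 that became 0.08 under spike-in centring. Of 20 contractile genes, 9 fell (9 adjusted over the list alone; camera adjusted p = 0.000790, and adjusted p = 0.282 with an estimated correlation), the median of -0.35 becoming 0.15 under spike-in centring, and Tcap fell by 1.31 ± 0.24. Of 14 endothelial markers, 6 fell (7 adjusted over the list alone; camera adjusted p = 0.00156, and adjusted p = 0.136 with an estimated correlation), with Gpihbp1 at -1.48 ± 0.19, and the median of -0.43 became 0.07 under spike-in centring. Of 15 clock genes, 3 fell (5 adjusted over the list alone; camera adjusted p = 0.00320, and adjusted p = 0.177 with an estimated correlation), with Nr1d1 at -1.59 ± 0.16, and the median of -0.43 became 0.07 under spike-in centring. Under spike-in centring 2 fatty acid oxidation, 3 branched chain (with 1 higher), 0 oxidative phosphorylation (1 higher), 0 TCA cycle, 2 contractile (5 higher), 1 endothelial (1 higher) and 2 clock genes (1 higher) were lower. Under poly-A centring the lower genes of these lists numbered 4, 5, 2, 0, 3, 2 and 2. On these arrays the macrophage marker median was 3.86.

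In all, 2247 genes rose and 2004 fell at 72 h, 1160 and 310 of them by at least 2-fold, with no overlap between the groups' arrays for 27.1% of genes. Under spike-in centring 7270 genes were higher and 247 lower, so that 96.7% of calls were rises, against 52.9% on the deposited scale, and under poly-A centring 590 were lower (82.3% rises).

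**Figure D2:**
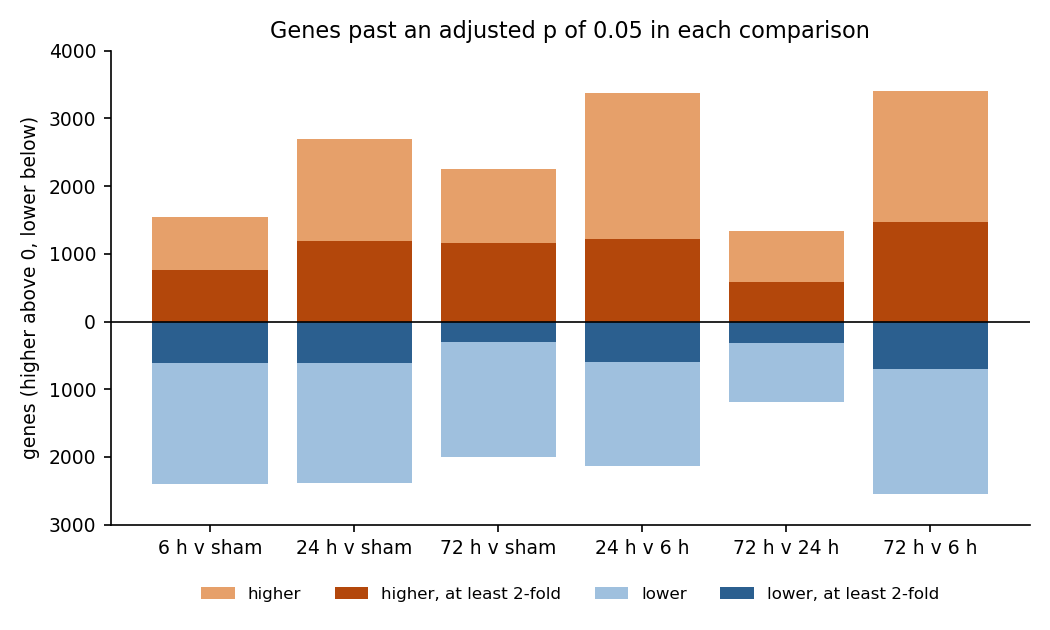
Number of genes past an adjusted p of 0.05 in each of the 6 comparisons, with higher genes drawn above 0 and lower genes below, and the part with a change of at least 2-fold in the darker shade, on the deposited scale. At 6 h 1545 genes were higher and 2395 lower than sham; under spike-in centring these counts were 975 and 3993, and at 24 h and 72 h the same centring changed 2701 and 2392 into 4546 and 841, and 2247 and 2004 into 7270 and 247.

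**Figure D3:**
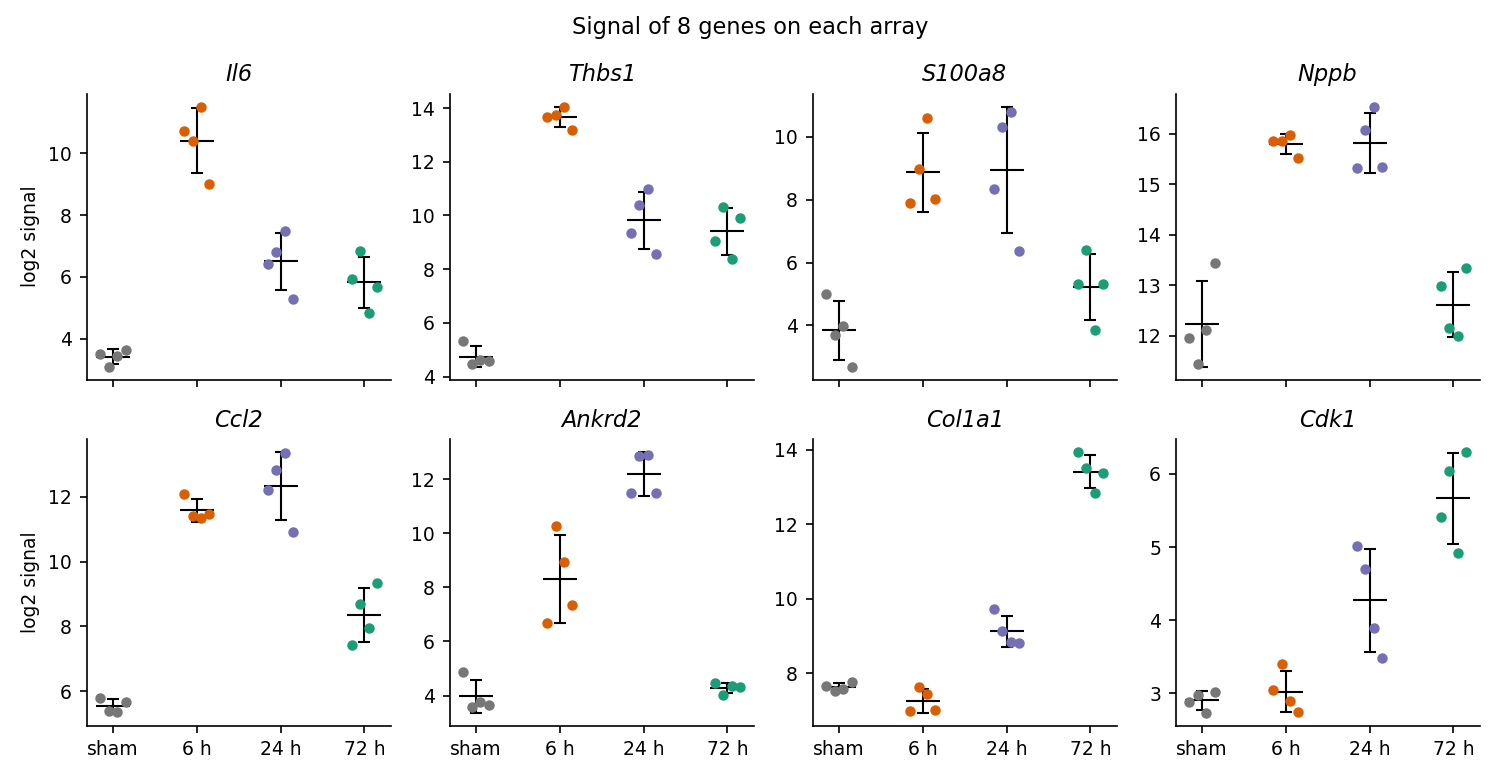
Log2 signal of 8 genes on each of the 16 arrays, with the mean and SD of the 4 arrays of each group as a bar and whiskers. Il6 and Thbs1 were highest at 6 h, Ankrd2 at 24 h, and Col1a1 and Cdk1 at 72 h, while Nppb had a mean of 15.80 at 6 h, 15.82 at 24 h and 12.61 at 72 h against 12.23 in sham.

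Between 6 h and 24 h, early-response and glucocorticoid-responsive genes fell and macrophage, matrix and replication genes rose. From 6 h to 24 h Pdk4 changed by -5.24 ± 0.28, Fam107a by -5.78 ± 0.24, the nuclear receptor Nr4a3 by -5.70 ± 0.28 and Atf3 by -4.94 ± 0.39, whereas Arg1 rose by 5.07 ± 0.53, Tnc by 4.79 ± 0.36 and Fn1 by 4.13 ± 0.39. Of 12 glucocorticoid response genes, 10 fell (10 adjusted over the list alone; camera adjusted p = 4.08e-12), the list call of this comparison that held with an estimated correlation (adjusted p = 0.00692). Of 15 immediate early genes, 14 fell (14 adjusted over the list alone; camera adjusted p = 4.08e-09, and adjusted p = 0.227 with an estimated correlation), while 8 were lower and 1 higher under spike-in centring. All 19 DNA replication genes rose (19 adjusted over the list alone; camera adjusted p = 7.77e-14, and adjusted p = 0.227 with an estimated correlation), with Mcm5 at 2.72 ± 0.35, and 15 of 18 macrophage markers rose (15 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.57e-09, and adjusted p = 0.310 with an estimated correlation). Of 24 fatty acid oxidation genes, 22 fell (23 adjusted over the list alone; camera adjusted p = 2.21e-10, and adjusted p = 0.334 with an estimated correlation), against 3 lower and 1 higher under spike-in centring and 8 lower under poly-A centring. Arg1 and Mcm5 at 6 h and Fam107a and Nr4a3 at 24 h were below background. In this comparison 3372 genes rose and 2135 fell (1214 and 597 by at least 2-fold), against 9811 and 539 under spike-in centring, which is 94.8% rises against 61.2%, and 831 lower (85.5% rises) under poly-A centring.

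Between 24 h and 72 h, muscle stress genes fell back and collagen, complement and mitosis genes rose. Ankrd2 changed by -7.89 ± 0.55, Nmrk2 by -6.22 ± 0.48 and the small heat shock protein gene Hspb1 by -4.59 ± 0.39, and Gpnmb rose by 5.83 ± 0.38, Cthrc1, a secreted protein of activated fibroblasts, by 4.78 ± 0.29, Mfap4 by 4.65 ± 0.42 and Col1a1 by 4.28 ± 0.22. Of 19 fetal and mechanical stress genes, 15 fell (17 adjusted over the list alone; camera adjusted p = 2.05e-21). Nppb changed by -3.20 ± 0.37. Fibrillar matrix genes rose in 16 of 22 cases (16 adjusted over the list alone; camera adjusted p = 7.25e-18) and complement genes in 10 of 13 (10 adjusted over the list alone; camera adjusted p = 1.00e-12). These 3 calls held with an estimated correlation, each with an adjusted p of 0.0293. Of 24 mitosis genes, 22 rose (22 adjusted over the list alone; camera adjusted p = 4.16e-19, and adjusted p = 0.0918 with an estimated correlation), while 6 of 19 DNA replication genes fell (10 adjusted over the list alone, 1 under either centring; camera adjusted p = 0.000313, and adjusted p = 0.401 with an estimated correlation) and 15 of 19 ribosome biogenesis genes fell (18 adjusted over the list alone; camera adjusted p = 6.33e-15, and adjusted p = 0.0871 with an estimated correlation). Neutrophil markers fell in 6 of 13 cases (9 adjusted over the list alone; camera adjusted p = 4.94e-06, and adjusted p = 0.345 with an estimated correlation). Macrophage markers rose in 7 of 18 cases and fell in 3 (8 and 3 adjusted over the list alone; camera adjusted p = 0.00151, and adjusted p = 0.528 with an estimated correlation), a call that ended without replicate 17 of the 24 h group (camera adjusted p = 0.0616, median 0.30 in place of 0.69): Ms4a7 rose by 3.28 ± 0.29 and Chil3 fell by 2.77 ± 0.65. Under either centring 2 of them were lower. Of 17 branched chain amino acid genes, 6 rose (8 adjusted over the list alone; camera adjusted p = 2.14e-05, and adjusted p = 0.345 with an estimated correlation), and 10 were higher under either centring. Counts were 1337 genes higher and 1183 lower (587 and 312 by at least 2-fold), with 463 lower under spike-in centring and 79.9% rises there against 53.1%, and 2624 higher and 401 lower (86.7% rises) under poly-A centring. Ankrd2 and Nmrk2 at 72 h and Cthrc1 at 24 h were below background.

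Between 6 h and 72 h Gpnmb, below background at 6 h, rose by 7.37 ± 0.38 and the collagens Col3a1 by 6.45 ± 0.29, Col1a2 by 6.26 ± 0.31 and Col1a1 by 6.15 ± 0.22. Hbegf changed by -6.60 ± 0.43 and the protease Adamts1 by -5.96 ± 0.31. Matrix genes rose in 19 of 22 cases and fell in 1 (19 and 1 adjusted over the list alone; camera adjusted p = 2.99e-18), and glucocorticoid response genes fell in 11 of 12 (11 adjusted over the list alone; camera adjusted p = 2.14e-11); both calls held with an estimated correlation (adjusted p = 0.0373 and 0.0102). In total 3409 genes rose and 2550 fell (1463 and 700 by at least 2-fold), against 13629 and 479 under spike-in centring, which is 96.6% rises against 57.2%, and 9167 and 621 (93.7% rises) under poly-A centring.

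**Figure D4:**
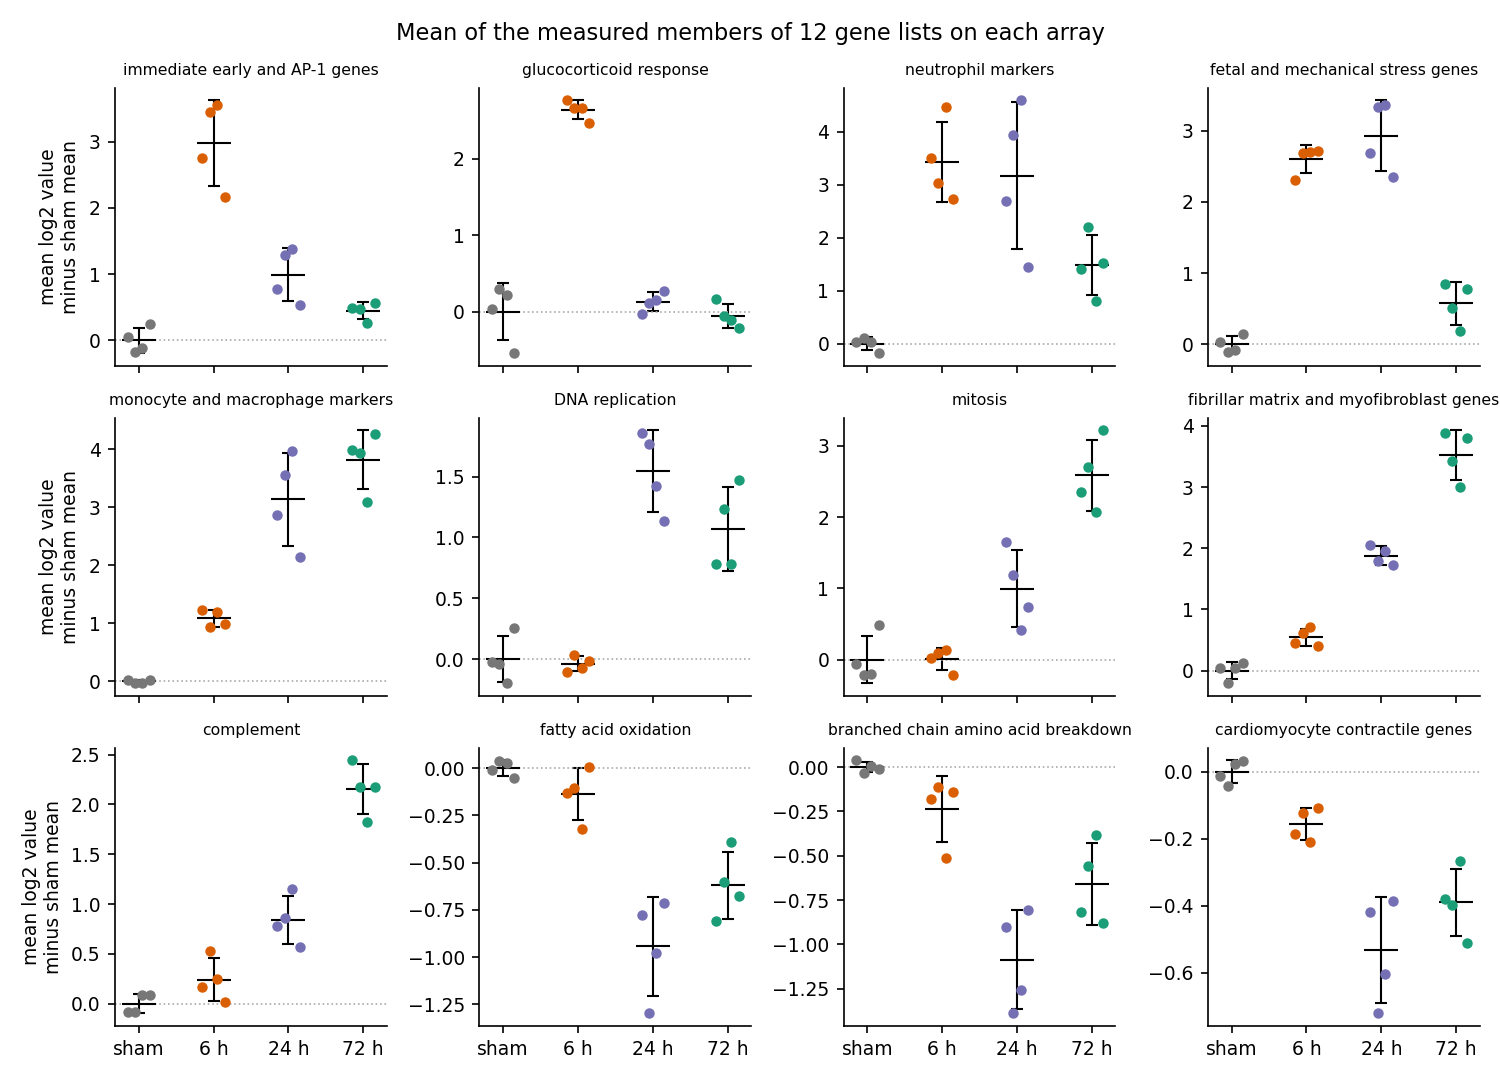
Mean log2 signal of the measured members of 12 gene lists on each array, relative to the mean of the sham arrays, with the mean and SD of the 4 arrays of each group. Immediate early and glucocorticoid response genes were highest at 6 h, and mitosis, matrix and complement genes at 72 h; fatty acid oxidation, branched chain and contractile genes were below sham at 24 h and 72 h on the deposited scale, although the contractile median at 72 h turned from -0.35 to 0.15 under spike-in centring.

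Genes were also sorted into classes by the tests against sham and between times; the classes overlap and do not name the time of the largest change. Among 4132 genes above sham at any time, 940 were early (6 h above sham and 72 h below 6 h), 421 middle (24 h above sham, 6 h and 72 h) and 1632 late (72 h above sham and above 6 h), with 22 genes both early and middle and 39 both late and middle. Early genes held 13 of 15 immediate early genes, 14 of 19 cytokine genes and 10 of 12 glucocorticoid response genes. The middle class held 9 of 19 ER stress genes and 9 of 30 proteasome subunits, and the late class held 23 of 24 mitosis genes, 19 of 22 matrix genes, 13 of 14 lysosome genes and 11 of 13 complement genes. Among 4574 genes below sham at any time, 1384 were early, 300 middle and 842 late (72 h below sham and below 6 h). That late class held 12 of 24 fatty acid oxidation genes and 15 of 35 oxidative phosphorylation genes, lists whose medians were lower at 24 h (-0.89 and -0.50) than at 72 h (-0.55 and -0.44). Middle genes above sham numbered 245 without replicate 15 of the 24 h group and 700 without replicate 17, and middle genes below sham 198 without replicate 15 and 199 without replicate 16. Late genes below sham numbered 547 without replicate 23 of the 72 h group.

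The 3 comparisons with sham share the sham arrays, and their calls overlapped. Both 24 h and 72 h had 1488 genes higher and 1185 lower, where independent lists would share 311 and 246. Simulated groups without any change, set against simulated sham arrays that the comparisons shared, had 0 and 0 in common. With the sham arrays split between the comparisons, 930 to 960 and 496 to 516 were shared. The 6 h and 24 h comparisons shared 807 higher and 868 lower genes (214 and 294 for independent lists, 0 and 0.02 simulated, 469 to 506 and 395 to 417 with split sham arrays), and 6 h and 72 h shared 496 and 636 (178 and 246 for independent lists, 0 and 0 simulated, 282 to 297 and 236 to 254 with split sham arrays). Part of each excess over these values may come from the shared sham arrays. Without changed genes the simulations give almost no calls, so their shared counts do not measure what the real sham arrays add. Across genes, which are not independent replicates, the covariance of the log2 changes was 0.326 for 24 h and 72 h, 0.216 for 6 h and 24 h and 0.128 for 6 h and 72 h. Shared simulated sham arrays gave 0.02. The correlations were 0.74, 0.51 and 0.31, against 0.50 in the simulations. In the 3 comparisons together, 430 genes were higher and 472 lower at all times; among them Timp1, below background in sham, was higher by 6.04, 8.95 and 8.18, and Hmox1 by 6.20, 4.57 and 5.83.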

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

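The tests on other splits of the arrays, the comparison of metabolic with contractile genes at equal level, and those of the medians and ranges of the 6 h arrays were chosen after the results they bear on had been seen. The genes named here with opposite changes were also chosen after their values were seen.

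In 9 of 280 tests of array measures, gene lists and genes fixed by name, 1 array of 4 stood apart from the other 3 of its group, where chance marks about 1 in 20 groups and would give 14. The measure is the gap of that array to its nearest neighbour as a share of the group's range. At 6 h, replicate 8 was lowest in the median of the negative controls (0.835) and highest in the hypoxia list (0.857), replicate 7 was lowest in the fetal and mechanical stress list (0.922) and highest in the interferon list (0.933) and in Ccl2 (0.859), and replicate 10 was lowest in the TCA cycle list (0.995). Replicate 15 of the 24 h group was lowest in endothelial markers (0.895), replicate 3 of sham lowest in glycolysis (0.947) and replicate 22 of the 72 h group lowest in Psmb8 (0.838). Among genes named by their size of change, 16 of 244 tests marked 1 array apart, against 12.2 by chance, and replicate 5 of sham was the array in 5 of them.

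Some genes passed the limma test in opposite directions at 2 times. At 6 h and 24 h these were 213 genes, 62 of them higher and then lower, such as Adh1, an alcohol dehydrogenase gene, at 3.31 ± 0.34 and then -1.94 ± 0.34, and the metalloproteinase inhibitor Timp3 at 2.04 ± 0.17 and then -1.88 ± 0.17. At 6 h and 72 h these were 280 genes, 76 of them higher and then lower, with the nuclear receptor Nr4a3 at 3.91 ± 0.28 and then -2.19 ± 0.28 (72 h mean below 6.76, the 75th percentile of the negative controls), Lyve1 at 1.23 ± 0.27 and then -1.56 ± 0.27, and the aminopeptidase Anpep at -1.64 ± 0.21 and then 2.99 ± 0.21. At 24 h and 72 h these were 61 genes, 20 of them higher and then lower, and the lipid transfer gene Pltp went from -1.56 ± 0.26 to 1.77 ± 0.26. Among the 2697 transcript clusters without a gene name here, which entered no comparison of the report, 64 were higher and 121 lower than sham at 6 h. At 24 h 180 were higher and 157 lower, and at 72 h 141 and 144. These calls made up 6.86%, 12.5% and 10.6% of the clusters, against 20.2%, 26.1% and 21.8% of the genes tested.

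The counts of genes past the threshold were set beside other splits: of the 35 ways to split the 8 arrays of a comparison into 4 and 4, only 1, the real one, gave as many genes. That is the smallest share that 35 splits allow. Other splits leave the difference between the groups in their spread, which lowers their counts. Splits also cannot tell reperfusion from any other difference that follows the groups, so no cause is drawn from them. The real counts and the highest of the other splits were 3940 and 0 for 6 h against sham, 5093 and 259 for 24 h against sham, 4251 and 1 for 72 h against sham, 5507 and 25 for 24 h against 6 h, 2520 and 3 for 72 h against 24 h, and 5959 and 0 for 72 h against 6 h. For the test among the 4 groups, 1 of 100 regroupings, the real one, gave 8677 genes, and the highest of the others gave 2920.

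At 24 h the fatty acid oxidation and branched chain lists had medians of -0.89 and -1.11 against -0.40 for contractile genes, on arrays where the macrophage marker median was 3.01. Dilution of cardiomyocyte RNA by RNA of incoming cells needs metabolic genes to fall no more than contractile genes. In a first test fatty acid oxidation and branched chain genes fell further (-0.41 and -0.55, each two-sided exact permutation p = 0.0286, n = 4 against 4, adjusted 0.0571 over 12 tests). This counted against dilution by the exact p, though not after adjustment. TCA cycle genes differed by -0.11 (the same p-values) and oxidative phosphorylation genes by -1.55e-05 (exact p = 1). The explanation was first worded as a smaller share of cardiomyocyte RNA and was reworded after the values were seen. The reason was that macrophage markers at 3.01 and endothelial markers at -0.29 moved apart, which argues against a lower cardiomyocyte share that raises all other cell types alike. A second test at equal sham level, made after the first because contractile genes are brighter, gave a difference of -0.0936 (exact p = 0.171), but it covers 17 of the 41 metabolic genes, those at a level of at least 14.5, beside 18 contractile genes, and has a slope of 0.23 on level that dilution alone does not predict, so dilution stays open and untested for the dimmer genes. Compression of bright signals needs metabolic genes as bright as the contractile median to fall no further than contractile genes, and for 18 such genes the difference of medians was -0.0115 (bootstrap interval over genes -0.18 to 0.24, added after the prediction and without effect on its outcome), with 77 dimmer metabolic genes at a median of -0.73. Compression, which bears on the gap between the lists and not on the falls themselves, stays open too, and a change in transcription with reperfusion, which the design names, stays open as untested.

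Of the circadian genes at 24 h, Arntl, Npas2 and Clock had a mean change of 1.11, while the mean of Dbp, Per3, Ciart, Nr1d1, Nr1d2, Tef and Hlf changed by -2.28 (each two-sided exact permutation p = 0.0286, n = 4 against 4, adjusted 0.0343 over 6 tests). The same means were 0.94 and -1.44 at 6 h, and -0.03 (exact p = 0.8) and -0.81 (exact p = 0.0286) at 72 h. Means below 6.76 were those of Arntl in sham, Ciart at 24 h, and Npas2, Tef and Hlf in both groups at 24 h. Opposite shifts of the genes of opposite phase are what collection at another time of day than sham would give. An effect on the clock itself could give them too, so the test cannot tell these apart. Collection at 24 h and at 72 h falls at the same hour of day if the hours of surgery were alike. The first mean nevertheless differed between these times, at 1.11 and -0.03. The hour of collection is not given in the sources used here. The test would have argued against collection at another hour had the first mean fallen by more than its spread. An effect of reperfusion on the clock itself stays open, as untested.

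At 6 h more genes fell than rose, 2395 against 1545, a ratio of 1.55. Genes near background are argued against as the whole of it by the ratio of 1.55 among genes above the 75th percentile of the negative controls. The ratio was 1.63 under median centring and 1.45 under quantile normalization, but these cannot decide on an array-wide scale difference or a narrower range of signal, because the deposited 6 h and sham arrays already had close medians (difference 0.0126, two-sided exact permutation p = 0.657, n = 4 against 4) and close 5th to 95th percentile ranges (0.0214, exact p = 0.657). Under spike-in and poly-A centring, added after the data were seen, 3993 and 6087 genes were lower and 975 and 864 higher. At 6 h the spike-ins were 0.22 and 0.34 higher than in sham, and the positive controls were at -0.23. Which of these controls follows the RNA content is not known. Scale and range therefore stay open beside an effect of reperfusion, which was not tested.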

How the results depend on the processing

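Spike-in centring, poly-A centring, the filter at the negative controls and the relations between hearts without replicate 16, or replicates 16, 21 and 23, were chosen after the data were seen, and the other alternatives were planned. Apart from spike-in and poly-A centring, every setting run over all 16 arrays, and fits of only the 2 groups compared, left each count of genes in the 6 comparisons within 1.5 times its reported value. Both centrings moved many counts. They shift all genes of an array alike, by spike-in means that differed between the groups. Under spike-in centring higher and lower genes numbered 975 and 3993 at 6 h (1148 lower by at least 2-fold), 4546 and 841 at 24 h (1964 and 288 by 2-fold), 7270 and 247 at 72 h (2385 and 56 by 2-fold), 9811 and 539 for 24 h against 6 h (3566 and 255 by 2-fold), 13629 and 479 for 72 h against 6 h (4930 and 260 by 2-fold), 463 lower genes for 72 h against 24 h, and 13748 genes among the 4 groups. Under poly-A centring they numbered 864 and 6087 at 6 h (491 and 1634 by 2-fold), 2033 and 2479 at 24 h, 2624 and 401 for 72 h against 24 h (1024 and 176 by 2-fold) and 9167 and 621 for 72 h against 6 h (3526 and 330 by 2-fold), with 590 lower at 72 h (155 by 2-fold), and 831 lower for 24 h against 6 h (2005 higher and 397 lower by 2-fold). With a minimum change of 2-fold the early, middle and late classes held 516, 212 and 931 genes above sham, and the early and late classes 473 and 183 below. With split sham arrays the shared genes numbered 469 to 506 higher and 395 to 417 lower for 6 h and 24 h, 282 to 297 and 236 to 254 for 6 h and 72 h, and 930 to 960 and 496 to 516 for 24 h and 72 h. The split leaves each comparison with fewer sham arrays and none in common, and which of these lowered the counts was not tested.

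Leaving out 1 array at a time gave 1331 to 1632 genes higher and 1865 to 2451 lower at 6 h, 2279 to 2948 and 1890 to 2616 at 24 h, and 1858 to 2320 and 1343 to 2097 at 72 h. The middle class above sham held 245 genes without replicate 15 of the 24 h group and 700 without replicate 17. The middle class below sham held 198 without replicate 15, 199 without replicate 16 and 377 without replicate 17. The late class below sham held 547 without replicate 23 of the 72 h group and 884 without replicate 17 of the 24 h group.

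Of 153 list calls, the estimated correlation ended 134, the filter at the median 14 of 146, spike-in centring 5, poly-A centring 2 and quantile normalization 1. Leaving out 1 array ended 32 of 2448. Under spike-in centring 20 list medians among these 153 calls went from below 0 to above it. These were endothelial markers at 24 h (0.0209), 72 h (0.0669) and from 6 h to 24 h (0.0243), contractile genes at 72 h (0.15), from 6 h to 24 h (0.26) and from 6 h to 72 h (0.50), and oxidative phosphorylation at 72 h (0.0516), from 6 h to 24 h (0.0497) and from 6 h to 72 h (0.33). The TCA cycle had 0.0771 at 72 h and 0.39 from 6 h to 72 h, heat shock genes 0.11 at 72 h and 0.0723 from 6 h to 72 h, clock genes 0.0704 at 72 h, and ubiquitin ligases of atrophy 0.0932 from 6 h to 24 h and 0.12 from 6 h to 72 h. From 6 h to 72 h endothelial activation had 0.13, fatty acid oxidation 0.24, branched chain genes 0.28 and the hypoxia list 0.17. Under poly-A centring 7 list medians among these 153 calls turned: NRF2 genes (-0.0179) and heat shock genes (-0.10) at 6 h and, from 6 h to 72 h, contractile genes (0.31), fatty acid oxidation (0.0457), oxidative phosphorylation (0.14), the TCA cycle (0.195) and branched chain genes (0.0850). Lists without a call are not counted here.

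Of 306 values of single genes, spike-in centring ended 3 calls, made 2 and turned 4 values, poly-A centring ended 1, made 2 and turned 3, trend and robust settings ended 1 call and median centring turned 2 values. Leaving out 1 array ended 11 of 4896 and turned 12. Each value that turned was uncalled. Cdk1 at 6 h was -0.10 with spike-in centring, -0.22 with poly-A centring and -0.0091 to 0.21 without single arrays, and Myh6 at 6 h was -0.0622 to 0.0435 without single arrays. Nppa at 6 h was -0.0027 with median centring, -0.21 with spike-in centring, -0.33 with poly-A centring and -0.14 to 0.22 without single arrays. Psmb8 at 6 h was -0.00073 with median centring, -0.21 with spike-in centring, -0.33 with poly-A centring and -0.0556 to 0.0806 without single arrays. Myh7 at 72 h was 0.0642 with spike-in centring. Beyond the construction of each setting, the cause was not tested.

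No paired analysis was possible because the groups share no replicate numbers. Alternatives set out before the data were examined but not run were other pseudocounts, since the values are on a log scale already, leaving out probe sets with nonspecific suffixes, of which the table has none, and separate actin and Gapdh controls, which were not used here. Signal over background limits part of the rises. Of the genes higher than sham, 284 at 6 h, 509 at 24 h and 520 at 72 h had both group means below the 75th percentile of the negative controls. Among rises of at least 2-fold, 286, 510 and 573 had the sham mean there, so that their size depends on the background.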

Other observations

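The 3 relations between hearts given here were chosen after the data were seen but before their values were computed, spike-in and poly-A centring and the relations without replicate 16 of the 24 h group or without replicates 16, 21 and 23 were added after the data were seen, and the gene lists and the other settings were fixed before the data were examined.

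Smooth muscle and pericyte markers were lower at 6 h: 6 of 12 fell (6 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0253, and adjusted p = 0.0865 with an estimated correlation), with Kcnj8, the pericyte channel subunit Kir6.1, at -0.96 ± 0.18 and the smooth muscle myosin gene Myh11 at -0.73 ± 0.16. That list call ended without replicate 8 of the 6 h group (camera adjusted p = 0.0525), over genes brighter than the array median (0.127) and with spike-in (0.0526) and poly-A centring (0.0674). At 24 h 4 of them fell and 2 rose (4 and 2 adjusted over the list alone, camera adjusted p = 0.484). Abcc9, a subunit that can partner Kir6.1, changed by -1.33 ± 0.14 while calponin (Cnn1) rose by 2.19 ± 0.53. Which cells the Abcc9 transcript came from was not tested. The list median of -0.09 became 0.21 under spike-in centring, with 4 higher and 2 lower. Of 17 hypoxia response genes, 4 rose and 3 fell at 6 h (6 and 4 adjusted over the list alone; camera adjusted p = 0.521), where Ddit4, an inhibitor of mTORC1, rose by 1.85 ± 0.34 and adrenomedullin (Adm) by 1.66 ± 0.36, while 4 were higher and 6 lower under either centring. At 24 h 2 rose and 8 fell (3 and 8 adjusted over the list alone; camera adjusted p = 0.110), among them the oxygen-sensing hydroxylase Egln1 at -1.21 ± 0.15, the mitophagy receptor Bnip3 at -1.12 ± 0.22 and the angiogenic factor Vegfa at -1.10 ± 0.22; under spike-in centring 4 were higher and 4 lower. At 72 h 1 rose and 7 fell (1 and 7 adjusted over the list alone; camera adjusted p = 0.0685), with Egln3 at -1.79 ± 0.31, and the median of -0.26 became 0.23 under spike-in centring, with 3 higher and 2 lower. In sham, Ddit4 and Cnn1 were below 6.76, the 75th percentile of the negative controls.

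At 72 h 8 of 18 ferroptosis and iron genes rose and 3 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.00402, and adjusted p = 0.136 with an estimated correlation), a call that ended over genes brighter than the array median (0.0507); 11 were higher and 1 lower under spike-in centring, and 8 and 2 under poly-A centring. The oxidase subunit Cybb rose by 3.49 ± 0.25, the ferritin light chain Ftl1 by 3.25 ± 0.26, the polyamine enzyme Sat1 by 2.00 ± 0.27 and transferrin (Trf) by 1.78 ± 0.21, and Cybb is also a gene of phagocytes, whose markers rose on the same arrays. Mesothelial and epicardial markers rose in 3 of 10 cases at 72 h (3 adjusted over the list alone; camera adjusted p = 0.0180, and adjusted p = 0.135 with an estimated correlation), with the retinoic acid enzyme Aldh1a2 at 3.22 ± 0.21, and that call ended without replicate 22 of the 72 h group (camera adjusted p = 0.0866), with 7 higher under spike-in centring. Of 12 T and NK cell markers, 0, 1 and 1 were higher and 1, 2 and 0 lower at 6 h, 24 h and 72 h (0, 1 and 1 higher and 0, 2 and 0 lower adjusted over the list alone; camera adjusted p = 0.888, 0.891 and 0.405), and the interleukin 7 receptor gene Il7r rose by 1.37 ± 0.36 at 24 h and 1.85 ± 0.36 at 72 h. Under spike-in centring 3 of these markers were higher at 24 h and 7 at 72 h, with 0 lower and medians of 0.33 and 0.56 in place of 0.02 and 0.06. Under poly-A centring 1 was higher and 2 lower at 24 h, with a median of -0.08, and 2 were higher at 72 h. In sham, Aldh1a2 and Il7r were below 6.76. Of 11 ubiquitin ligases of muscle atrophy, 3 rose and 3 fell at 6 h (4 and 3 adjusted over the list alone; camera adjusted p = 0.441), with a median of 0.01 (-0.21 under spike-in and -0.33 under poly-A centring). At 24 h 0 rose and 3 fell (0 and 4 adjusted over the list alone; camera adjusted p = 0.00685, and adjusted p = 0.179 with an estimated correlation), with a median of -0.38 (-0.07 under spike-in and -0.48 under poly-A centring). Fbxo32 in this list changed by -1.90 ± 0.37 at 6 h and -1.34 ± 0.37 at 24 h.

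Hearts of 1 time point differed from each other, and a candidate explanation is that the extent of injury differed between hearts. If it did, list means should move together across the 12 reperfused arrays after each is centred on its time point, and 3 such relations were computed with 1e+05 resamples within time points. Neutrophil and macrophage markers had a Pearson r of 0.863 (permutation p = 0.0043, adjusted 0.0129) and a Spearman rho of 0.77 (permutation p = 0.02), with r = 0.658 without the 2 arrays farthest from the median. Each time point has 4 arrays, too few for an r of its own, and without the arrays of 24 h r was 0.556, against 0.918 without 6 h and 0.93 without 72 h. Macrophage markers and fatty acid oxidation genes had r = -0.716 (permutation p = 0.05, adjusted 0.075) and rho = -0.825 (permutation p = 0.012), with r = -0.51 without the 2 farthest arrays and -0.674 to -0.747 without 1 time point, which leaves this relation undecided. Macrophage markers and matrix genes had r = 0.53 (permutation p = 0.086, adjusted 0.086) and rho = 0.538 (permutation p = 0.13), and r = 0.0756 without the 2 farthest arrays, so that this relation rests on those. Without the arrays of 72 h that r was 0.281, and without those of 24 h it was 0.825. Replicate 16 of the 24 h group had a mean of 2.00 for atrial markers relative to sham, against -0.43 to 0.04 on the other 24 h arrays, and without it the r of the 3 relations, in the order given, were 0.796, -0.829 and 0.577. At 72 h the atrial gene Myl4 was at 9.76 and 9.44 on replicates 21 and 23, against 7.69 and 7.75 on the other 2 arrays, and Myl7 at 6.07 and 6.18 against 3.58 and 4.19. Without these 3 arrays, which leaves 9, r was 0.844, -0.886 and 0.524. The first relation may reflect unequal injury, but an unequal share of injured tissue in the piece taken would give it too. The atrial transcripts of replicates 16, 21 and 23 are a sign that the pieces were not alike, and the injured share of each piece was not measured.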
